A study of Penaeus vannamei with 6 samples.

How the data were processed

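Hepatopancreas RNA from 6 shrimp libraries, 3 from PBS-injected and 3 from *Vibrio parahaemolyticus*-injected animals, was sequenced on an Illumina HiSeq instrument, per the labels and the series' design text. Total RNA was extracted with Trizol from snap-frozen tissue, per the labels' protocols. The design text names 3 biological replicates in each group and does not say how many animals made up a library. Time after injection, dose, tank and batch are not given in the sources used here, so a tank or batch that followed the groups cannot be separated from the injection. Libraries were assigned to groups and replicate numbers from their titles and treatment labels.

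The authors deposited 1 table with a read count and an FPKM value for each of 24486 features in each library. The deposited read counts are estimated (expected) counts, since between 49.4% and 50.3% of the values in a library are not whole numbers. By the unit in the file headers, the deposited FPKM values are read counts divided by feature length and library size, rounded to 2 decimals. The unit does not say whether the length was reduced for fragment size. RSEM 1.2.15 and DESeq 1.10.1 are named in the submitters' processing notes, without their role. The read filter, assembler or reference, aligner and strand setting are not given in the sources used here. Estimated counts divide reads that fit several similar sequences, so the level of a feature with a close copy is uncertain. The lowest FPKM value is 0.31 in every library and 0 values lie at or under 0.3, so a feature close to 0 FPKM in any library is outside this table. Changes between absence and presence are therefore counted only in part.

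Features carry cluster numbers, and 23513 of them share the first number 18806. Of these IDs, 0 matched the reference table of 27905 genes, and the table pairs no ID with a name. The 25 gene lists fixed before the data were examined (immune, digestive, metabolic and cell type groups) matched 0 features, so their planned set tests gave no value. Under the naming rule fixed at the same time, with no names in the table, only the 2 risers and 2 fallers with the smallest adjusted p are given by ID. The tests of the sets raised or lowered at least 256-fold, of the 10 and 100 most abundant features, and of reads outside the table were chosen after the values were seen.

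Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, quasi-likelihood fit and test, no covariate). Features were filtered with filterByExpr at its defaults (minimum count 10, minimum total count 15), which left 22597 and removed 1889. A feature was called at a Benjamini-Hochberg adjusted p under 0.05. At an unadjusted p under 0.05 there were 9103 features. The standard error of a fold change was taken from the quasi-likelihood F statistic. The biological coefficient of variation was 27.3%. TMM-scaled library sizes were used for CPM, the normalised read count, and shares of reads use the deposited estimated counts over their sum. The share of the 10 most abundant features was compared with a two-sided exact permutation test of 3 libraries against 3, which cannot give a p below 0.1. Random sets matched on level were drawn 10000 times from the 50 features nearest in level, with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Figures were drawn with matplotlib 3.10.9.

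Library depth lay between 21537546 and 25131285 counted reads, and these totals cover the features in the table only. On data simulated from the means and library sizes of Vibrio against PBS, with 22312 features tested, the test recovered 8 of 97 features changed 2-fold (8.25%) and 74 of 97 changed 4-fold (76.3%), with 3 false calls among 85. A 2-fold change was thus often not detectable where few features changed. No pair of libraries within a group agreed within sampling noise (chi-square per degree of freedom from 26.0 to 94.6), so each library was counted as 1 replicate.

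Alternatives fixed before the data were examined were RLE and upper-quartile scaling, DESeq2 1.42.0, limma 3.58.1 (trend) on log2(FPKM + 1), no filter on low counts, at least 50 reads in 3 libraries, an adjusted p under 0.01 with a 2-fold change, the replicate number as a block, and leaving out each library in turn. Fits without the features changed at least 256-fold, and shares of the FPKM sum, were added after the data were seen. Features named in the table by number only were not matched to sequence, and no genome was used here.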

Results

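RNA was sequenced from the hepatopancreas, the digestive gland, of Pacific white shrimp (*Penaeus vannamei*, also called *Litopenaeus vannamei*) at the intermolt stage. Healthy shrimp had been assigned at random to injection with sterile phosphate-buffered saline (the PBS group) or with *Vibrio parahaemolyticus* (the Vibrio group), a marine bacterium that infects shrimp. Each group held 3 libraries, described by the submitters as biological replicates. The table listed 24486 features, each under a cluster number with no gene name, description or sequence, so features are described here by their level and change and not by function. Total estimated counts were 24503483, 22914660 and 22000880 in PBS replicates 1, 2 and 3, and 25123163, 21537546 and 25131285 in Vibrio replicates 1, 2 and 3.

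The comparison of the Vibrio group with the PBS group asked how the hepatopancreas transcriptome responded to inoculation with the bacterium. After Vibrio injection 3251 features rose and 2835 fell, together 26.9% of the 22597 features tested. The risers had a median log2 fold change of 1.26 (quartiles 0.90 and 1.77) and the fallers one of -1.18 (quartiles -1.61 and -0.86). At least a 2-fold change was seen in 2195 risers and 1805 fallers, and at least an 8-fold change in 169 risers and 80 fallers. Among these, 28 features rose and 3 fell by 256-fold or more. These calls came from edgeR's quasi-likelihood test on rounded estimated counts, with a Benjamini-Hochberg adjusted p under 0.05 and 3 libraries in each group. Leaving out PBS replicate 1 lowered the number of fallers to 1662, and leaving out PBS replicate 2 lowered it to 1568. Risers made up 53.4% of the calls, against 46.9% with upper-quartile scaling and 63.5% with limma on the FPKM values.

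The libraries separated by injection. The first principal component held 64.9% of the variance of log2 CPM (normalised read counts scaled to library size) and the second 11.3%. The correlation across features lay between 0.955 and 0.971 for the 6 pairs of libraries within a group and between 0.867 and 0.907 for the 9 pairs across groups. Features are not independent replicates, so these correlations carry no test. In 10489 features (46.4%) all 3 values of one group lay above all 3 of the other, where chance gives 10%, and 6054 of these features were among the calls.

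With the tested features ordered by mean level and divided into 5 classes of equal size, 229 rose and 339 fell in the lowest class. In the next classes upward, 503 rose and 417 fell, then 747 and 486, then 960 and 598. In the most abundant class, 812 rose and 995 fell. The share of features called was 12.6% in the lowest class and 39.98% in the highest, while the median absolute log2 fold change of the called features was 1.49 and 0.98, so smaller changes passed the test where counts were higher.

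**Figure D1:**
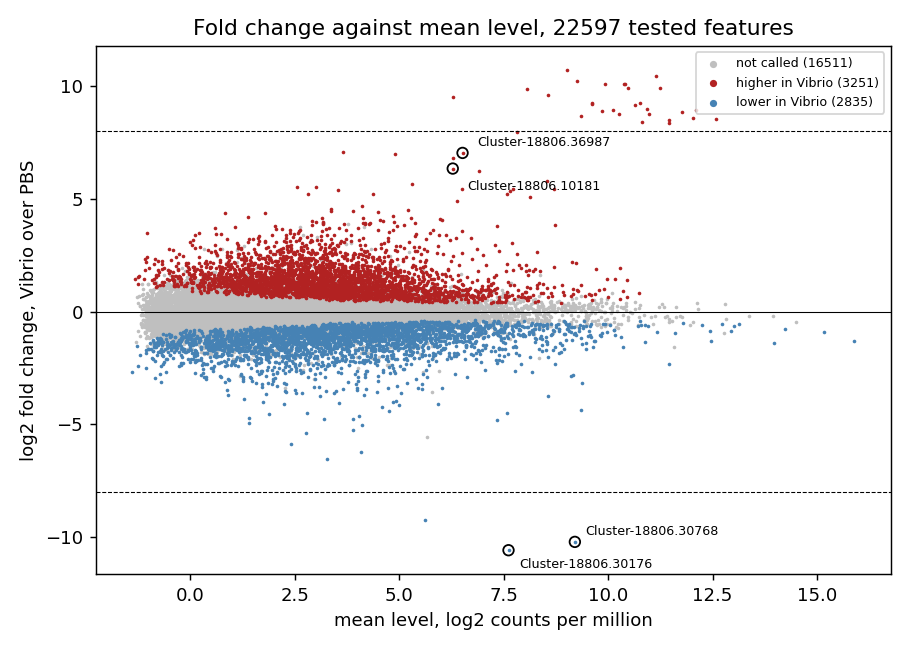
Log2 fold change of Vibrio over PBS against mean level in log2 CPM, with each point standing for 1 tested feature, red for risers (3251), blue for fallers (2835) and grey for features not called; dashed lines mark 256-fold. The 28 largest rises lie above the upper dashed line, with the next riser at 7.94, and the circled features are those given by ID in the text.

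The 2 risers with the smallest adjusted p were Cluster-18806.36987 and Cluster-18806.10181. Cluster-18806.36987 was at 1.39 ± 0.26 CPM (SD, n = 3) in the PBS group and at 181 ± 11.2 (SD, n = 3) in the Vibrio group. Its log2 fold change was 7.03 (SE 0.20, edgeR adjusted p = 8.38e-06), and it was higher in all 3 Vibrio libraries than in any PBS library. Cluster-18806.10181 went from 1.90 ± 0.42 to 154 ± 8.68 CPM (SD, n = 3), a log2 fold change of 6.33 (SE 0.21, edgeR adjusted p = 1.94e-05). All 6 estimated counts of each of these features were whole numbers, within 0.005 of a read.

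The 2 fallers with the smallest adjusted p were Cluster-18806.30768 and Cluster-18806.30176, both abundant in the PBS group and close to undetected in the Vibrio group. Cluster-18806.30768 fell from 1179 ± 8.52 to 1.0 ± 0.13 CPM (SD, n = 3), with a log2 fold change of -10.20 (SE 0.19, edgeR adjusted p = 1.14e-06). Its estimated counts were 26640, 25701 and 25826 in PBS replicates 1, 2 and 3 and 23, 23 and 29 in Vibrio replicates 1, 2 and 3. Cluster-18806.30176 fell from 392 ± 32.9 to 0.26 ± 0.10 CPM (SD, n = 3), with a log2 fold change of -10.57 (SE 0.28, edgeR adjusted p = 7.87e-06). Its Vibrio values rest on 4, 7 and 8 reads, so the size of the fall is less precise than its direction. With limma on log2(FPKM + 1), where the added 1 shrinks changes from low levels, the log2 fold changes were 5.40 for Cluster-18806.36987, 5.43 for Cluster-18806.10181, -9.46 for Cluster-18806.30768 and -9.24 for Cluster-18806.30176.

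The 28 features raised at least 256-fold held a large part of the reads in the Vibrio libraries. Their log2 fold changes ran from 8.35 to 10.70 with edgeR adjusted p from 3.87e-05 to 0.00337, and the next riser stood at 7.94. Together they took 10.2% ± 3.96 (SD, n = 3) of all counted reads in the Vibrio group, with 8.30%, 14.8% and 7.54% in Vibrio replicates 1, 2 and 3. In PBS replicates 1, 2 and 3 they took 0.00828%, 0.00787% and 0.0442%. As a share of the FPKM sum, which counts long features less, the same features took 5.36% ± 2.18 (SD, n = 3) in the Vibrio group. Ratios between replicates were taken on counts over the library total, without TMM scaling. Each of the 28 features kept nearly the same ratio between Vibrio replicates 3 and 1, from 0.877 to 0.964. The ratio of replicate 2 to replicate 1 ran from 1.36 to 2.33 over the 28 features. Whole numbers made up 17.9% of their estimated counts, against 23.5% for the 500 most abundant other features. A value that is not whole includes reads divided among similar sequences, so the level of a single member of this set is uncertain. The set was chosen after the values were seen and for its difference between the groups, so a test of its share between the groups carries no weight and is not given.

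**Figure D2:**
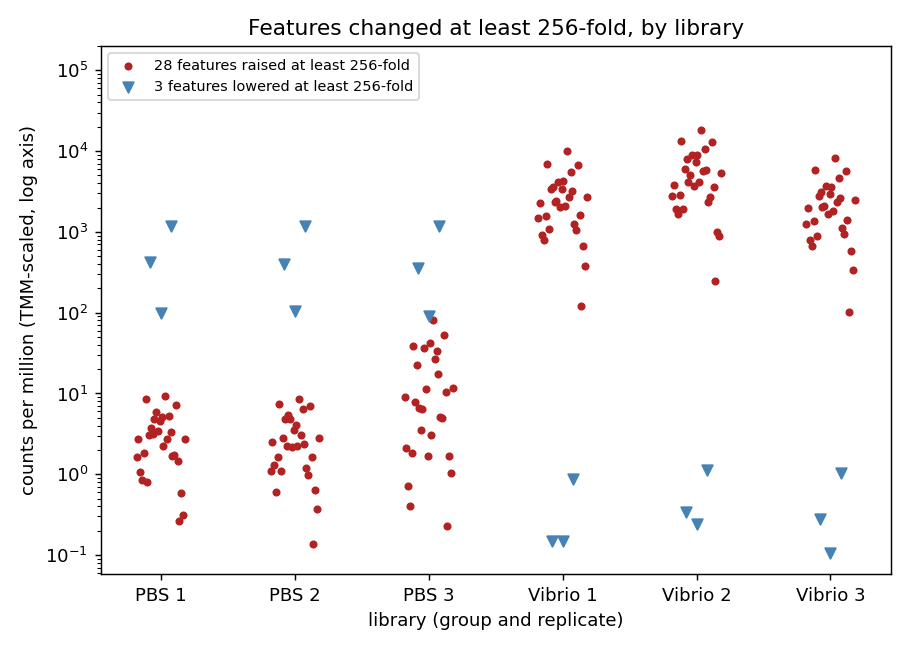
TMM-scaled CPM (log axis) of the 28 features raised and the 3 features lowered at least 256-fold, by library; each point stands for 1 feature. Without TMM scaling, 18 of the raised features lie at least 3-fold higher in PBS replicate 3 than in PBS replicate 1. The other 10 do not. In the Vibrio libraries all 28 raised features lie highest in replicate 2.

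The 10 most abundant features took a smaller share of reads after Vibrio injection. The 10 features with the highest mean level held 25.5% ± 2.26 (SD, n = 3) of the reads in the PBS group and 15.3% ± 0.94 (SD, n = 3) in the Vibrio group. The difference of 10.2 percentage points was larger than the spread within either group (two-sided exact permutation p = 0.1, the smallest possible here). The most abundant feature of all went from 8.24% ± 1.44 to 3.61% ± 1.27 of the reads (SD, n = 3; log2 fold change -1.30, SE 0.34, edgeR adjusted p = 0.0288). Of these 10 features 7 fell and 0 rose, and all 10 had a negative fold change under every scaling tried. Only 2 of the 10 were still called without PBS replicate 1, or without PBS replicate 2, and 0 at an adjusted p under 0.01 with a 2-fold change. Over the 100 most abundant features, 24 rose, 25 fell and 51 were not called, with a median log2 fold change of -0.20 (Fisher's exact p = 0.567 across features, against the other calls). By the same Fisher's exact test the lean to lower values gave p = 0.00474 for the 10 most abundant features and p = 3.88e-06 for the 500 most abundant, of which 88 rose and 141 fell; features are not independent replicates. Of the 24 that rose, 17 belonged to the set raised at least 256-fold. The number of the 100 that fell was 13 without PBS replicate 1 and 9 without PBS replicate 2.

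**Figure D3:**
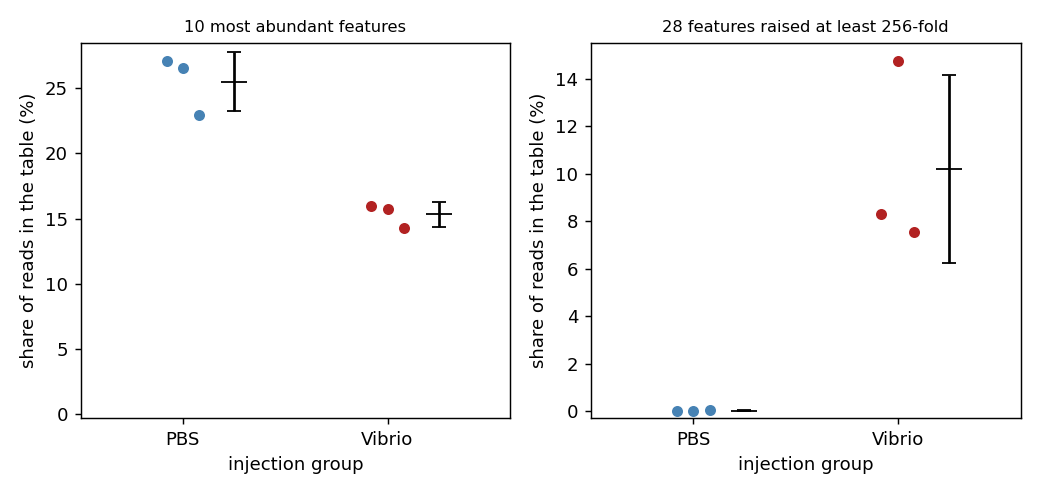
Share of counted reads (%) in the 10 most abundant features (left) and in the 28 features raised at least 256-fold (right), by injection group; coloured points are single libraries, and black marks give the mean ± SD of 3 libraries. The left panel shows 25.5% in the PBS group against 15.3% in the Vibrio group, and the right panel shows a mean of 10.2% in the Vibrio group, which is 5.36% as a share of the FPKM sum.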

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

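Fits without the features changed at least 256-fold, shares of the FPKM sum and leaving out libraries from the shares were chosen after the results were seen. At an adjusted p under 0.01 with a 2-fold change, 1293 features rose and 906 fell, fewer by construction. Leaving out 1 library gave 2316 to 2956 risers and 1568 to 2213 fallers (1662 without PBS replicate 1, 1568 without PBS replicate 2), with fewer libraries in each fit. Of the calls, 3286 (2043 risers, 1243 fallers) were kept in all 6 such fits. In the other settings the counts stayed within 1.5 times of the reported ones, and 0 called features changed sign in any setting. With the replicate number as a block there were 2580 risers and 2229 fallers. Same-numbered libraries did not deviate together across features (correlations -0.01, 0.03 and -0.07), so no pairing was seen. A shared tank or batch with a small effect cannot be excluded by these values. The 4 named features were called in every setting that tested them, with highest adjusted p 0.000268 to 0.000426. On the FPKM sum, the fall in the share of the 10 most abundant features was 7.29 percentage points and the Vibrio share of the 28 raised features 5.36%; the cause was not tested. As shares of reads, without 1 library, they were 9.40 to 11.5 points and 7.92% to 11.5%. The pseudocount alternative was planned for a table with no counts and was not run, and the gene lists matched 0 features.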

Other observations

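The tests on the features raised at least 256-fold were chosen only after the result was seen. The tests of the share of abundant features and of reads outside the table were added after the data were seen but before their own results were known.

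In Vibrio replicate 3, 17 features with at least 50 reads stood at least 8-fold above every other library, against 2 in Vibrio replicate 2, 2 in PBS replicate 3 and 0 in each of the other libraries. The 3 features lowered at least 256-fold stood at 0.0426% to 0.247% of their PBS level in the single Vibrio libraries. Cluster-18806.30768 stood at 0.0812%, 0.0947% and 0.102% in Vibrio replicates 1, 2 and 3, and Cluster-18806.30176 at 0.0426%, 0.0869% and 0.0851%. The 28 raised features stood at medians of 0.0787% and 0.0765% of their Vibrio level in PBS replicates 1 and 2. Whether leaked reads make up the Vibrio counts of these fallers was not tested, so the size of the falls is uncertain.

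Of the 10 splits of the 6 libraries into 3 and 3, only the real one gave as many calls (1 of 10, with 6086 features), and the highest of the other splits gave 0 with edgeR. The other splits had 309 to 720 features at an unadjusted p under 0.05, against 9103 for the real one. With so few splits a share under 0.05 cannot be reached. Each other split also put PBS and Vibrio libraries on both sides, so the difference between the groups raised the spread within each side. Few calls would follow there in any case, so the other splits are no null comparison.

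The 28 features raised at least 256-fold varied together across the Vibrio libraries. The SD of their log2 ratio between replicates 3 and 1 was 0.0380, where random sets of the same level had a median of 0.430. For the ratio of replicate 2 to replicate 1 the SD was 0.156 against a median of 0.486. For each ratio 0 of 10000 random sets were as low, so a shared source or a shared control is a candidate explanation. The random sets took the 28 as separate features. Only 17.9% of their estimated counts were whole, against 23.5% for the 500 most abundant other features. Reads divided among similar sequences can also make features vary together, and this was not tested. The 28 next-largest called rises varied more, with SDs of 2.05 and 0.720, so large rises were not all even across the Vibrio libraries. Reads that leaked from the Vibrio libraries may make up the counts of the 28 raised features in PBS replicates 1 and 2. There these features stood at a median of 0.0787% and 0.0765% of the Vibrio level. The range between the 10th and 90th percentile of the features was at most 1.66-fold, but a trace of the same source would look alike. Picking features raised at least 256-fold also caps this share, and features near 0 FPKM are outside the table, which removes low shares. A narrow range can thus come in part from the selection. In PBS replicate 3 that range was 9.02-fold around a median of 0.326%, which argues against leakage as the whole cause there. A trace of 1 source in fixed proportions would not give that range either. Of the 28 features, 18 had a ratio of at least 3 between PBS replicates 3 and 1, and 10 had a ratio under 2. These values rest on 1 library. Whether the 28 raised or the 3 lowered features are shrimp transcripts or RNA from another organism was not tested, since no sequence was used. For both sets, a response to the injection and an unrecorded difference between the groups stay open.

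The 10 most abundant features lost 10.2 percentage points of the reads in the Vibrio group, while the 28 raised features gained as much. With the 28 removed from every total, the shares were 25.5% ± 2.25 in the PBS group and 17.1% ± 1.55 in the Vibrio group (SD, n = 3), a difference of 8.41 points, or 82.6% of the original. Displacement of reads by the 28 features therefore accounts for a part of the fall and not for all of it. The limit of 80 percent set for this test was passed by less than the spread, but the 8.41 points left exceed the 5.09 below which displacement was to count as the cause, by more than the SD of either group. In the fit without the features changed at least 256-fold, 8 of the 10 fell. That fit hardly differed from the main one (3247 risers and 2833 fallers, against 3251 and 2835), so it adds no weight against displacement. Whether a different mix of cells contributes was not tested.

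If FPKM was divided by all counted reads, which the sources used here do not state, FPKM values and counts together show reads counted outside this table, here over 6271 well-covered features in 5 classes of length. In the longest, the implied total exceeded the PBS mean by 1.97%, 3.40% and 2.00% in Vibrio replicates 1, 2 and 3, and by -0.03%, 0.10% and -0.07% in the PBS libraries, a difference of 2.46 percentage points between the groups. The difference grew with length, with 0.61, 1.75, 2.10, 2.30 and 2.46 points from the shortest class to the longest, and in the shortest class Vibrio replicate 3 (-0.76%) lay below every PBS library. Reads outside the table alone would give the same difference in each class, so an effect of length on short features is present too, but a difference in fragment length fades as features get longer, which argues against it as the cause of the excess in the longest class. More reads from features left out of the table in the Vibrio group stay open as an explanation, and a feature near 0 FPKM in the PBS libraries would be among those left out.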
